A study of Homo sapiens with 6 samples.

How the data were processed

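The data were gene counts of 6 RNA-seq libraries from MCF-7 cells, 3 treated with 10 µM enterolactone and 3 with 0.1% DMSO for 72 h. Per the labels' protocols, cells were moved 48 h after seeding to phenol red-free medium with charcoal-stripped serum for 24 h, and treated with medium renewed every 24 h. Messenger RNA was captured with a KAPA kit, libraries were made with the KAPA RNA HyperPrep kit with oligo-dT primed cDNA synthesis, and sequencing gave paired reads of 150 bases on a NextSeq instrument, per the labels' protocols. The labels call the samples replicates by number and do not say that they came from separate cultures. The p-values of single genes thus measure only the spread between these samples, which may be technical.

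The deposited table holds whole-number gene counts for 58735 Ensembl gene identifiers in 1 column per library. Reads were handled with FastQC 0.11.5, Trimmomatic 0.36, STAR 2.7.6a and featureCounts 2.0.0 on the GRCh38 build, per the submitters' processing notes. The strand setting, the gene annotation release and the treatment of reads that map to several places were not given in the sources used here. The 58735 identifiers are the same set as those of GENCODE 29, which was used for coordinates, transcript length and GC content, and symbols came from a table of gene names that matched 42465 identifiers. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart: of the 106 named genes tested, 20 share exonic bases with another tested gene, and 0 share 50% or more of them with any one gene by direct count of bases. Families of near-identical copies (histones, metallothioneins, heat shock genes) are reported as uncertain.

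Total counts ran from 10899966 to 20645676 per library, and 26624 genes had no count in any library. Genes were kept by edgeR's filterByExpr by group, which left 15091. Counts were scaled with TMM factors and tested in R 4.3.3 with edgeR 4.0.16's quasi-likelihood test on treatment alone, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are counts scaled to library size with the TMM factors. Standard errors were derived from the same fit's test, as the absolute log2 fold change over the square root of the F statistic. They therefore restate the p-value and the fold change. The biological coefficient of variation was 19.4%.

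Gene lists were compared with the rest of the genes by limma 3.58.1's camera with a preset correlation of 0.01, adjusted over the 34 lists tested, and again with an estimated correlation, with which 0 of the 11 called lists held (lowest adjusted p 0.0574, against 11 with the preset value). By fry, a directional rotation test, 8 of the 11 passed, among them the oestrogen-induced list (adjusted p = 0.0438), and 3 did not: oestrogen-repressed genes (0.0709), immediate early genes (0.121) and histones (0.142). Camera p-values with the preset correlation compare genes with genes and do not measure the spread between samples. For the oestrogen-induced list the unadjusted camera p was 2.77e-11. It was 6.26e-10 when DMSO 1, enterolactone 2 and enterolactone 5 were set against the other libraries, a split that mixed the treatments. Of 718 listed genes 717 were matched to the table. Test, samples, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 12 largest increases and 12 largest decreases among called genes with mean log2 CPM of at least 1, separated groups and a proper symbol; ESR1, ESR2, GPER1, TFF1, PGR, GREB1, PDZK1, CCND1, MKI67, MYC and CYP1A1 always; and for each list up to 4 called members with the smallest p, or up to 3 members as values where none was called. Other list members named in the report (MYB, CXCL12, PKIB, ELOVL2, TPD52L1, LAMA3, GLA and CD44) are the rest of small counts and were named after their values were seen.

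The procedure was tested on simulated data with the real means and library sizes, for enterolactone against DMSO on 14811 genes with 200 changed. It recovered 97.0% of genes changed 4-fold, 41.8% of those changed 2-fold and 11.9% of those changed 1.5-fold, and 5 of 105 calls were false (4.76%). With no gene changed, edgeR made 0 calls, 5.12% of genes had an unadjusted p below 0.05, and 0 of 34 lists were called by camera. Genes were simulated independently of each other, so this does not show how camera behaves when the genes of a list are correlated. In the real data the estimated correlation was 0.18 for the G2/M list and 0.57 for the DNA repair list. The samples simulated up to here also had no structure beyond treatment. A split of the real libraries that mixed the treatments gave 1260 edgeR calls. The simulated share of false calls thus need not hold for the real data. GC trends were then added as straight lines of set slope, not as measured in the libraries, and without a length trend (14780 genes). Here 0 of 89 calls of the uncorrected fit and 6 of 118 of the corrected fit were false. The 2 fits recovered 92.4% and 95.5% of 4-fold changes, 40.9% and 68.2% of 2-fold changes and 1.54% and 6.15% of 1.5-fold changes.

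Alternatives were RLE scaling, no filter, a filter of 50 counts in at least 3 libraries, DESeq2 1.42.0, limma-voom, a block on the replicate number, a 2-fold threshold, leaving out each library in turn, camera with an estimated correlation and fry. Added after the data were seen were removal of each library's loess trend on GC content and transcript length (span 0.4), the same with the block, the sign of each library's GC trend as a term beside treatment, and a comparison of only the 4 libraries left without DMSO 1 and enterolactone 5, the ends of the GC gradient. The fixed list of 13 mitochondrially encoded mRNAs was left out because each was listed at 0. Raw reads were not used here.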

Results

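Polyadenylated RNA of MCF-7 cells was sequenced in 6 libraries, 3 from cells exposed to enterolactone and 3 from cells given the vehicle. MCF-7 is a human breast cancer line that carries oestrogen receptor alpha, and enterolactone is a lignan that gut bacteria make from plant precursors and that is classed as a phyto-oestrogen. The cells were kept in hormone-depleted, phenol red-free medium for 24 h and then received 10 µM enterolactone or 0.1% DMSO for 72 h. Total counts per library were 20645676, 11336359 and 14272800 for DMSO replicates 1, 2 and 5, and 20227922, 10899966 and 13369864 for enterolactone replicates 2, 4 and 5. Protein-coding genes held 97.6% to 97.9% of the counts, and the 10 most abundant genes of a library held 5.59% to 6.75%. All 37 genes of the mitochondrial genome were listed at 0 in every library, so the fixed list of 13 mitochondrially encoded mRNAs was not tested.

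The single comparison in the design asked which transcripts differ genome-wide between enterolactone and vehicle. TFF1, a secreted trefoil peptide and standard marker of oestrogen receptor activity, rose 7.52-fold with enterolactone. It went from 52.7 ± 3.65 to 396 ± 78.9 CPM (counts scaled to library size, mean ± SD, n = 3 each). Of 38 measured oestrogen-induced genes 10 rose (camera adjusted p = 2.35e-10, and 0.298 with an estimated correlation). Without DMSO 2 the count was 1, with a list median log2 fold change of 0.48 against 0.46. That median was 0.27 without DMSO 5 and 0.34 without enterolactone 5. Of 30 G2/M and mitosis genes 25 rose and of 30 G1/S and DNA replication genes 23 did, counts that became 6 and 3 without DMSO 2, while their median log2 fold changes of 1.84 and 1.11 became 1.73 and 1.09. Both lists passed camera, and with an estimated correlation the adjusted p was 0.0574 and 0.202. Of 22 DNA repair genes 12 rose, and 0 by edgeR without DMSO 2, with all 22 still positive (adjusted p = 0.260 with an estimated correlation). Of the genes that fell, RASD1 and APOD kept their call without each library, while ACHE, CCN2, IGFBP3 and TIMP3 lost theirs without DMSO 2. Fewer genes fell than rose (154 and 395), which turned without DMSO 5 (485 and 387).

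Across the 15091 genes tested, 549 passed the 0.05 threshold of the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment (3.64%), of which 395 rose and 154 fell with enterolactone. A change of at least 2-fold was reached by 283 of the genes that rose and 57 of those that fell. At an unadjusted p below 0.05 edgeR gave 3238 genes, and DESeq2 called 797 higher and 487 lower, and limma-voom 316 and 143. In all 549 genes the 3 enterolactone values lay on one side of the 3 DMSO values, which 25.7% of all tested genes did and chance gives for 10%. Genes are called for such a difference between groups, so the separation of the 549 lends them no further support. The count depended on single libraries: 92 rose and 22 fell without DMSO 1, 41 and 5 without DMSO 2, 387 and 485 without DMSO 5, 844 and 335 without enterolactone 2, 82 and 15 without enterolactone 4, and 158 and 39 without enterolactone 5. Fold changes also followed base composition, with a Spearman correlation of -0.41 across genes between log2 fold change and transcript GC content, where genes are not independent replicates. After removal of each library's GC and length trend 689 genes rose and 573 fell, and 511 of the 549 kept their call and sign. With the sign of each library's GC trend as a term beside treatment, 907 rose and 595 fell, including all 549.

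**Figure D1:**
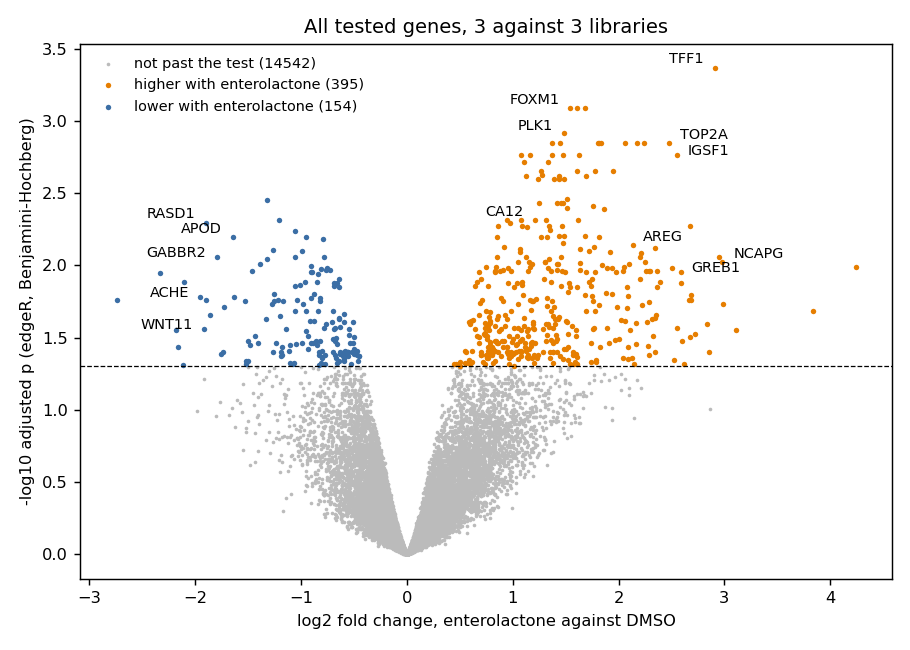
Each point is one of 15091 genes, with the log2 fold change of enterolactone against DMSO on the horizontal axis and -log10 of the edgeR adjusted p on the vertical axis, and the dashed line marks 0.05. Orange marks the 395 genes that rose and blue the 154 that fell, and TFF1 lies highest at a log2 fold change of 2.91.

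The oestrogen-induced list held 40 genes known as induced by oestradiol in this cell line, of which 38 were measured, 33 had a positive log2 fold change and 10 rose. TFF1 (ENSG00000160182, GRCh38 chromosome 21, 42362282 to 42366594) had a log2 fold change of 2.91 ± 0.16 (SE), adjusted p = 4.33e-04. GREB1 (ENSG00000196208, chromosome 2, 11482341 to 11642788), an oestrogen receptor cofactor, rose by 2.59 ± 0.39 (adjusted p = 0.0111) from 25.8 ± 3.27 to 155 ± 95.6 CPM. AREG, a ligand of the epidermal growth factor receptor, rose by 2.13 ± 0.28 (adjusted p = 0.00718), and CA12, a carbonic anhydrase, rose by 1.21 ± 0.14 (adjusted p = 0.00482). The other called members were MYB, CXCL12, PKIB, ELOVL2, TPD52L1 and XBP1, with log2 fold changes of 2.01, 1.79, 1.32, 1.20, 0.70 and 0.64. The list's median log2 fold change was 0.46, and camera placed it above the other genes with adjusted p = 2.35e-10. With an estimated correlation between genes the adjusted p was 0.298. Adjusted over the list alone, 16 members rose and 2 fell, and after GC and length correction 14 rose and 2 fell. XBP1 was no longer past the threshold after the correction (0.56 ± 0.17 against 0.64 ± 0.12 before, edgeR adjusted p = 0.0727). The 10 called members became 3 without DMSO 1, 1 (TFF1) without DMSO 2, 4 without enterolactone 4 and 4 without enterolactone 5. The list's median was 0.27 without DMSO 5, with 27 members positive, and 0.34 without enterolactone 5, with 29 positive. GREB1 lost its call without DMSO 1 (adjusted p = 0.0505) or DMSO 2 (0.0824), and AREG (0.0711) and CA12 (0.0590) without DMSO 2.

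Several genes fixed for their link to oestrogen signalling did not pass the threshold in the full comparison. PGR, the progesterone receptor, had a log2 fold change of 2.18 ± 0.53 at a low level (0.607 to 2.55 CPM; adjusted p = 0.0619, and 0.0441 after GC and length correction). ESR1, which encodes oestrogen receptor alpha, had 0.47 ± 0.11 (adjusted p = 0.0551, and 0.28 ± 0.08 with 0.0707 after the correction), and GPER1, a membrane receptor for oestrogens, had 0.74 ± 0.19 (0.0719, and 0.0360 after the correction). CCND1, the cyclin of early G1, was negative at -0.38 ± 0.10 (0.0677, and 0.0296 after the correction), and the proto-oncogene MYC had -0.11 ± 0.14 (0.687). ESR2, which encodes oestrogen receptor beta, had counts of 4, 1 and 2 in DMSO and 0, 3 and 6 in enterolactone, and PDZK1, an oestrogen-induced scaffold gene, had 6, 7 and 7 against 10, 12 and 31, so both fell short of the filter on low counts. In the list of genes repressed by oestrogen, 1 of 18 fell and 0 rose by edgeR (list-wide median -0.38, camera adjusted p = 4.30e-04; adjusted p = 0.355 with an estimated correlation and 0.0709 by fry). The member that fell was PSCA, a cell surface antigen, at -1.17 ± 0.20 (adjusted p = 0.0176), and its call ended without DMSO 1, DMSO 2 or enterolactone 4, leaving 0. Without enterolactone 2 the count was 5. Adjusted over the list alone 3 fell, and after GC and length correction 1 fell.

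**Figure D2:**
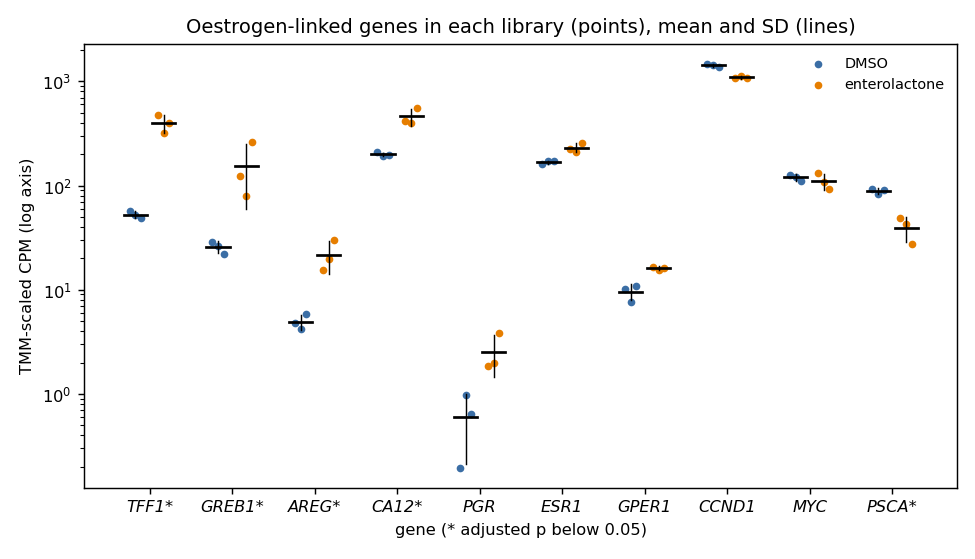
TMM-scaled CPM on a log axis for 10 genes linked to oestrogen signalling, with 1 point per library (3 DMSO in blue, 3 enterolactone in orange), the mean as a horizontal line and the SD as a vertical line, and an asterisk on genes past the 0.05 threshold. TFF1 lies at 52.7 CPM in DMSO and 396 in enterolactone on average, while MYC overlaps between the groups.

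The G2/M and mitosis list had the largest median of the 34 lists tested, 1.84, with all 30 members positive and 25 called (camera adjusted p = 9.34e-59; adjusted p = 0.0574 with an estimated correlation). FOXM1 (ENSG00000111206, chromosome 12, 2857681 to 2877155), a transcription factor of the G2/M programme, rose by 1.54 ± 0.11 (adjusted p = 8.15e-04) from 60.6 ± 3.55 to 176 ± 9.25 CPM. PLK1, a mitotic kinase, rose by 1.49 ± 0.11 (0.00122), TOP2A, the topoisomerase of dividing cells, by 2.48 ± 0.21 (0.00142), and BIRC5, which encodes survivin, by 1.37 ± 0.12 (0.00142). MKI67, which encodes the Ki-67 proliferation antigen, had a value of 2.02 ± 0.48 that did not pass (adjusted p = 0.0561). All 30 rose when adjusted over the list alone, and 26 after GC and length correction. The 25 became 13 without DMSO 1, 6 without DMSO 2 and 10 without enterolactone 4. FOXM1, PLK1, TOP2A and BIRC5 remained called without each of the 6 libraries in turn.

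In the G1/S and DNA replication list the median was 1.11 and 23 of 30 rose (camera adjusted p = 2.05e-38; adjusted p = 0.202 with an estimated correlation). The members with the smallest p were TK1, thymidine kinase, at 1.27 ± 0.13 (adjusted p = 0.00237), GINS1, a subunit of the replicative helicase, at 1.13 ± 0.11 (0.00240), TYMS, thymidylate synthase, at 1.46 ± 0.16 (0.00367) and CDC45, a helicase cofactor, at 1.52 ± 0.17 (0.00404). CCND1 was the one member with a negative value. There were 28 that rose and 1 that fell (CCND1) when adjusted over the list alone, and 26 and 1 after GC and length correction. The 23 became 10 without DMSO 1, 3 without DMSO 2, where CDC45 lost its call, and 10 without enterolactone 4.

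DNA repair genes had a median of 1.43 and 12 of 22 rose (camera adjusted p = 5.92e-21; adjusted p = 0.260 with an estimated correlation). Examples were FANCA and FANCD2 of the Fanconi anaemia pathway, at 1.08 ± 0.13 (adjusted p = 0.00482) and 2.21 ± 0.34 (0.0124), and RAD54L and XRCC2 of homologous recombination, at 1.44 ± 0.18 (0.00630) and 1.89 ± 0.28 (0.0104). A total of 18 rose when adjusted over the list alone and 15 after GC and length correction. Without DMSO 1, DMSO 2 and enterolactone 4 the count was 2, 0 and 2, without enterolactone 5 it was 7, and without enterolactone 2 it was 19. Exons of FANCA overlap those of ZNF276 on the opposite strand for 23.6% of their length, exons of RAD54L those of LRRC41 for 25.1%, and exons of TYMS those of ENOSF1 for 39.2%, and whether the counting used strand was not given in the sources used here.

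**Figure D3:**
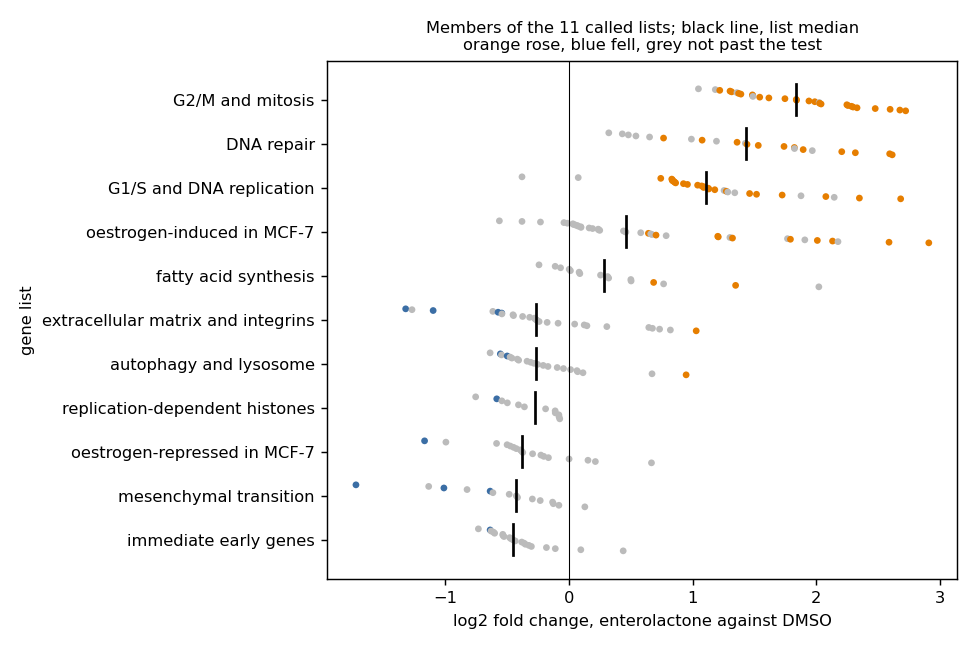
Log2 fold change of every measured member (points) of the 11 lists past the camera threshold, with the list median as a black line, orange for members that rose, blue for those that fell and grey for those not past the gene-level test. The G2/M, G1/S and DNA repair members lie almost wholly above 0, with medians of 1.84, 1.11 and 1.43, while the 6 lower lists have medians between -0.45 and -0.26.

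Among called genes with a mean log2 CPM of at least 1 and separated groups, the 12 with the largest increase were NCAPG, TFF1, KIF4A, MCM10, SPDL1, KIF23, SLC6A14, EXO1, BUB1B, BLM, GREB1 and IGSF1, from 2.98 down to 2.55 on the log2 scale. NCAPG (ENSG00000109805, chromosome 4, 17810902 to 17844862), a subunit of condensin, rose by 2.98 ± 0.42 (adjusted p = 0.00946) from 0.461 ± 0.175 to 3.61 ± 1.33 CPM, and LCORL overlaps 33.1% of its exonic bases. SLC6A14, an amino acid transporter, rose by 2.67 ± 0.45 (0.0173), and IGSF1, an immunoglobulin superfamily gene, by 2.55 ± 0.24 (0.00172). NCAPG and SLC6A14 lost their calls without DMSO 1, DMSO 2 or enterolactone 4, with the adjusted p of NCAPG then at 0.0536, 0.0714 and 0.0538. KIF4A, MCM10, SPDL1, EXO1, BUB1B and BLM also lost theirs without DMSO 1, DMSO 2 or enterolactone 4. Their DMSO means were low, from 0.582 CPM (BLM) to 1.18 CPM (MCM10). EXO1 stood at 11.8 CPM in enterolactone 5 against 2.95 in enterolactone 2, and KIF4A at 11.4 against 4.4. IGSF1 kept its call without each library.

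The 12 largest decreases were those of ACHE, WNT11, RASD1, NCF2, GABBR2, DHRS3, CDH5, CCN2, APOD, PCSK2, SLIT1 and NR2F1, from -1.95 to -1.50 on the log2 scale. ACHE (ENSG00000087085, chromosome 7, 100889994 to 100896974), acetylcholinesterase, fell by 1.95 ± 0.32 (adjusted p = 0.0164) from 63.2 ± 22.5 to 16.3 ± 5.35 CPM. RASD1, a Ras-related GTP-binding protein induced by glucocorticoids, fell by 1.90 ± 0.23 (0.00512) from 66.2 ± 11.6 to 17.8 ± 4.65 CPM, and APOD, a lipid-binding apolipoprotein, fell by 1.64 ± 0.21 (0.00637) from 241 ± 72.2 to 77.2 ± 10.3 CPM. RASD1 and APOD were the only ones of these 12 to keep their call without each library. ACHE lost its call without DMSO 1, DMSO 2, enterolactone 4 or enterolactone 5. Of the 63 named genes past the threshold, 23 kept their call without DMSO 1, 11 without DMSO 2, 57 without DMSO 5, 63 without enterolactone 2, 20 without enterolactone 4 and 37 without enterolactone 5.

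Lists of matrix and mesenchymal genes were lower. Of 15 measured mesenchymal transition genes 3 fell and 0 rose by edgeR, with a median of -0.43 (camera adjusted p = 8.66e-06; adjusted p = 0.355 with an estimated correlation). The 3 were the matricellular genes CCN2 at -1.72 ± 0.30 (adjusted p = 0.0194) and CCN1 at -0.64 ± 0.14 (0.0458), and TGFBI, a matrix protein induced by TGF-beta, at -1.01 ± 0.16 (0.0136). Of 27 extracellular matrix and integrin genes 4 fell and 1 rose, with a median of -0.26 (camera adjusted p = 0.00206; adjusted p = 0.260 with an estimated correlation). TIMP3, a metalloproteinase inhibitor, fell by 1.32 ± 0.18 (0.00900), the collagen gene COL5A1 by 1.10, and the integrin genes ITGA3 and ITGB5 by 0.57 and 0.54, while the laminin gene LAMA3 rose by 1.03. When adjusted over the list alone, 6 mesenchymal genes fell, and 8 matrix genes fell and 1 rose. After GC and length correction 4 mesenchymal genes fell, and 7 matrix genes fell and 1 rose. The mesenchymal count became 0 without DMSO 1, DMSO 2 or enterolactone 4. The matrix count that fell became 1 without DMSO 1, enterolactone 4 or enterolactone 5, 0 without DMSO 2 and 9 without DMSO 5, and LAMA3 kept its call only when enterolactone 2 was the library left out.

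Immediate early genes, which respond first to growth and stress signals, had a median of -0.45, and 1 of 21 fell, which was CCN1 (camera adjusted p = 2.63e-05; adjusted p = 0.387 with an estimated correlation and 0.121 by fry). The numbers were 6 that fell and 1 that rose when adjusted over the list alone, and 5 and 1 after GC and length correction, and the count that fell was 4 without DMSO 5 or enterolactone 2 and 0 without any other library. Of 22 autophagy and lysosome genes 2 fell and 1 rose, with a median of -0.27 (camera adjusted p = 0.00294; adjusted p = 0.260 with an estimated correlation). LAMP1, a lysosomal membrane protein, fell by 0.50 ± 0.10 (adjusted p = 0.0380), SQSTM1, an autophagy receptor, fell by 0.56 ± 0.12 (0.0400), and the lysosomal galactosidase gene GLA rose by 0.95. Adjusted over the list alone 7 fell and 2 rose, and after GC and length correction 5 fell and 2 rose. LAMP1, SQSTM1 and GLA lost their calls without DMSO 1, DMSO 2, enterolactone 4 or enterolactone 5, where 0 members of the list fell by edgeR. MRNIP overlaps 20.7% of the exonic bases of SQSTM1.

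Replication-dependent histone genes had a median of -0.28, all 12 measured members were negative and 1 fell, H2BC21 at -0.58 ± 0.13 (adjusted p = 0.0414; camera adjusted p = 0.00167 for the list; adjusted p = 0.457 with an estimated correlation and 0.142 by fry). Adjusted over the list alone 4 fell, and after GC and length correction 2 did. The list's adjusted p was 0.0729 without DMSO 5 and 0.147 without enterolactone 5, and the count of members that fell was 0 without any one library apart from enterolactone 2, where it was 2. These genes are near-identical copies whose reads can be split in counting, and most of their mRNAs lack a poly(A) tail, so single values are uncertain. Fatty acid synthesis genes had a median of 0.28 and 2 of 16 rose (camera adjusted p = 0.0220; adjusted p = 0.260 with an estimated correlation). The 2 were ACACB, an acetyl-CoA carboxylase, at 1.35 ± 0.19 (adjusted p = 0.00900) and the desaturase gene FADS1 at 0.68 ± 0.12 (0.0220). The count was 3 when adjusted over the list alone and 4 after GC and length correction. The list's adjusted p was 0.0522 with the stricter filter and 0.0729 without DMSO 5, and the count that rose was 0 without DMSO 1, DMSO 2 or enterolactone 4 and 1 without enterolactone 5.

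The remaining 23 lists did not pass the camera threshold, although some held called members. In the hypoxia and glycolysis list (adjusted p = 0.0822, median -0.13) 2 of 26 fell, the prolyl hydroxylase gene EGLN3 by 0.98 and the hexokinase gene HK2 by 0.58, and the list passed without DMSO 5 (0.0369) or enterolactone 2 (0.0214). In the insulin and IGF signalling list (0.793) 1 of 20 fell, IGFBP3, an IGF-binding protein, by 1.46 ± 0.22 from 414 ± 44.5 to 150 ± 46.1 CPM (adjusted p = 0.0109), a call that ended without DMSO 2 or enterolactone 4. In the drug metabolism list (0.134, median -0.16) the efflux pump gene ABCC3 was the 1 of 9 that fell, by 0.75. That list passed by fry (adjusted p = 0.00392). Among 13 androgen and glucocorticoid receptor targets (0.156, median -0.04) TMPRSS2 fell by 0.84, TSC22D3 fell by 0.96 and the metallothionein gene MT2A rose by 1.13, a value that is uncertain as its family holds near-identical copies, and MT2A was also the 1 of 6 that rose in the metallothionein list (0.113, median 0.30). Among 24 genes of the unfolded protein and integrated stress response (0.494, median -0.09) XBP1 and the serine synthesis gene PHGDH rose by 0.64 and 0.77, and XBP1 was the 1 of 20 luminal identity genes that rose (0.844). Among 24 p53 targets (0.961, median 0.01) MDM2 rose by 0.80 ± 0.17, a call lost after GC and length correction as the fold change shrank (0.36 ± 0.10, adjusted p = 0.0552), and the polymerase gene POLH by 0.75. HSP90AA1, a chaperone whose close paralogs make its value uncertain, was the 1 of 15 heat shock genes that rose, by 0.91 (0.755, median 0.23). Of the 14 called genes that the naming rule gave for these lists and those of other cell types, all 14 lost their call without DMSO 2, 12 without DMSO 1, 3 without DMSO 5, 13 without enterolactone 4 and 9 without enterolactone 5.

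For lists of other cell types, the basal breast list (adjusted p = 0.162, median -0.48) had 1 of 8 higher, CD44 by 1.15, and 1 lower, CAV2 by 0.60, and the endothelial list (0.183, median -0.30) had 1 of 3 lower, CDH5 by 1.74. The fibroblast (0.755, median -0.17; 4 measured) and leukocyte (0.183, median -0.59; 2 measured) lists had 0 called genes by edgeR, with VIM at 1.02 CPM in DMSO and 0.732 in enterolactone and CD74 at 0.970 and 0.693. Lists with 0 called members by edgeR also included aryl hydrocarbon receptor targets (0.0881, median -0.25), with CYP1A1 at -0.94 ± 0.26 (adjusted p = 0.0920), cytosolic ribosomal proteins (0.1104, median -0.11), with RPL10A at -0.21, and type I interferon genes (0.455, median 0.34), with OAS3 at 0.51 (0.0782). The same held for NRF2 antioxidant targets (0.134, median -0.09) and apoptosis regulators (0.147, median -0.13), both of which passed after GC and length correction (adjusted p = 0.0493 for each), with HMOX1 at -0.50 (0.158) and BMF at -0.50 (0.0965) in the full comparison. It held too for ribosome biogenesis and MYC targets (0.343, median 0.20), with NME1 at 0.50 (0.0787), NF-kB genes (0.399, median -0.07), with ICAM1 at -0.70 (0.0629), and cholesterol synthesis (0.821, median 0.11), with EBP at 0.50 (0.0516) and LSS at -0.41 (0.0561). Alternatives brought some of these past the threshold: aryl hydrocarbon receptor targets without DMSO 1 (adjusted p = 0.0332), enterolactone 4 (0.0487) or enterolactone 5 (0.0349) and in 8 of 16 alternatives in all (0.00230 to 0.295), ribosomal proteins without enterolactone 2 (0.00453), NRF2 targets without enterolactone 5 (0.0217) and in 5 of 16 in all, and leukocyte markers without enterolactone 4 (0.0104), all downward. For epithelial junctions (0.563; median 0.07, mean -0.0030, test downward), insulin and IGF signalling (median 0.04, mean 0.02, test downward), luminal identity (median -0.04, mean 0.01, test downward) and nuclear oxidative phosphorylation (0.961; median 0.04, mean 0.06, test downward) the signs of median, mean and test differed.

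**Figure D4:**
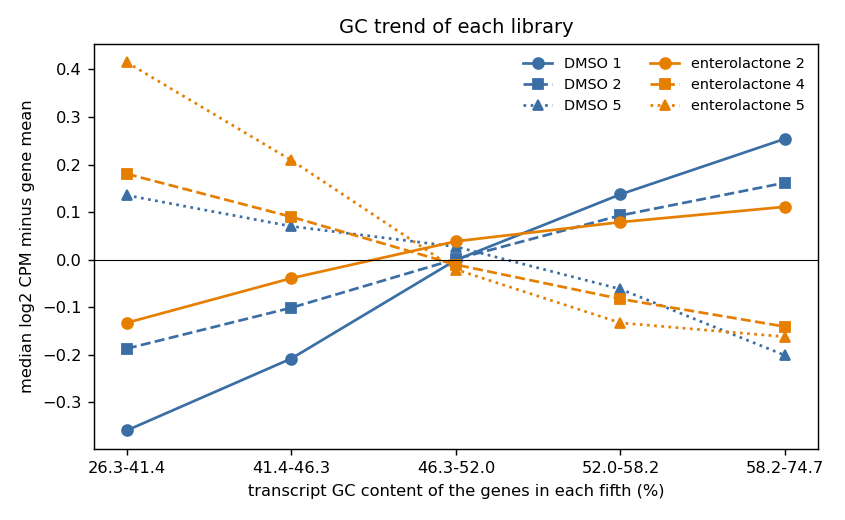
Median log2 CPM minus the gene's mean over all 6 libraries (vertical axis) in 5 bins of genes ordered by transcript GC content in percent (horizontal axis), 1 line per library, blue for DMSO and orange for enterolactone. In the bin of lowest GC content DMSO 1 lies at -0.36 and enterolactone 5 at 0.41, with DMSO 5 and enterolactone 2 on the opposite side of 0 from the rest of their groups.

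The GC trend differed between libraries of the same group as well as between groups. The Spearman correlation across genes of each library's deviation with GC content was 0.62, 0.45 and -0.37 for DMSO 1, 2 and 5 and 0.31, -0.45 and -0.50 for enterolactone 2, 4 and 5. Genes that rose had a median transcript GC content of 45.3%, those that fell 52.0% and all tested genes 49.0%. With only DMSO 2, DMSO 5, enterolactone 2 and enterolactone 4, 61 genes rose and 7 fell, and of the lists 13 G2/M, 4 G1/S, 4 oestrogen-induced and 0 DNA repair genes rose by edgeR. The medians of these 4 lists were then 1.53, 0.87, 0.41 and 1.07, against 1.84, 1.11, 0.46 and 1.43 with all libraries.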

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

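The GC and length correction, alone or with the replicate block, the term for the sign of each library's GC trend and the 4-library comparison were chosen after the data were seen; the other alternatives were planned. Of the 395 and 154 genes called higher and lower, the counts became 1261 and 473 with no filter, 797 and 487 with DESeq2, 689 and 573 after GC and length correction, 237 and 81 after that correction with the replicate block, 907 and 595 with the GC trend sign as a term, and 61 and 7 with the 4 libraries; leaving out 1 library in turn gave 41 to 844 higher and 5 to 485 lower. The replicate block left 322 higher and 91 lower (and, alone or with the GC correction, 0 of the 2 autophagy and lysosome genes that fell), and the 2-fold threshold left 57 lower. Only numbers 2 and 5 occur in both groups, with deviation correlations of 0.13 and 0.36 (0.57 for DMSO 1 with enterolactone 2), and with 2 such pairs the numbers were not taken to pair the samples, which leaves open whether they do. The share of calls that were higher moved from 71.9% to 54.6% after GC correction, to 60.4% with the GC sign term and to 44.4% without DMSO 5. The called genes kept their sign wherever they had a value, and their call in 525 of 549 with RLE scaling, 541 with DESeq2, 455 with limma-voom, 511 after GC correction, 549 with the GC sign term, 335 with the replicate block and 67 with the 4 libraries. Fewer samples leave less power in the last. With the block, DMSO 1 and enterolactone 4 have no library of their number in the other group. The treatment effect there rests on DMSO 2 and 5 and enterolactone 2 and 5. The oestrogen-induced list stayed higher and past the threshold in 16 reruns (camera adjusted p from 4.19e-19 to 3.68e-06) and with fry (0.0438), and not by camera with an estimated correlation (0.298). Its estimated correlation was 0.22, against the preset 0.01. The autophagy and lysosome list, with an estimated correlation of 0.0027, went from a camera adjusted p of 0.00294 to 0.260. A larger correlation thus cannot be the only reason that such calls ended, and the cause was not tested. Of the other called lists, the histone and fatty acid lists each lost their call in 2 of the 16 reruns, and the cause was not tested. With an estimated correlation 0 of the 11 called lists held. By fry, oestrogen-repressed genes, immediate early genes and histones did not pass. Of the uncalled lists, aryl hydrocarbon receptor targets passed in 8 of 16 settings, NRF2 targets in 5, hypoxia in 3, leukocyte markers in 2 of 15, and ribosomal proteins, metallothioneins, apoptosis regulators and basal markers in 1 each. For aryl hydrocarbon receptor targets these included the replicate block alone (camera adjusted p = 0.00320) and with the GC correction (0.00661). In simulated data the uncorrected fit recovered 41.8% of 2-fold changes, so absence from the calls is no sign of an unchanged gene.

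Results that changed sign were past the threshold neither before nor after, and the cause was not tested. With the replicate block, adjusted p was 0.733 for cholesterol synthesis, 0.886 for luminal identity and 0.733 for nuclear oxidative phosphorylation; with the GC correction as well, 0.859 for luminal identity and 0.536 for nuclear oxidative phosphorylation. After GC correction alone it was 0.770 for luminal identity, 0.990 for p53 targets and 0.765 for nuclear oxidative phosphorylation. With the GC sign term it was 0.695 for cholesterol synthesis, 0.680 for luminal identity and 0.801 for nuclear oxidative phosphorylation. With the 4 libraries it was 0.969 for NF-kB genes, 0.622 for cholesterol synthesis, 0.587 for luminal identity and 0.876 for nuclear oxidative phosphorylation, and the log2 fold changes of CD74 and MYC were 0.0134 and 0.0487. For fibroblast markers it was 0.928 with the filter of 50 counts, and for nuclear oxidative phosphorylation 0.822 with no filter and 0.974 with limma-voom. Leaving out 1 library in turn gave 0.480 to 0.952 for fibroblast markers (reversed without enterolactone 2), 0.355 to 0.977 for cholesterol synthesis (without DMSO 1 or enterolactone 5), 0.305 to 0.995 for luminal identity (without enterolactone 5), 0.572 to 0.995 for p53 targets (without DMSO 5 or enterolactone 5) and 0.613 to 0.998 for nuclear oxidative phosphorylation (without DMSO 1, enterolactone 4 or enterolactone 5). The log2 fold change of MYC ran from -0.27 to 0.0015, reversed without enterolactone 5.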

Other observations

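The gene groups and genes in the first paragraphs, the GC tests of the calls, of the trend itself and of the histone list, the list medians without 2 libraries, the GC sign term and the list of TGF-beta targets were chosen after the result was seen. Among 8 protein complexes of chromosome and replication biology 25 of 38 members rose and 0 fell by edgeR and 6 of the 38 are also in the fixed lists; the complexes were chosen after the cell cycle genes were seen to rise, so these counts add no independent support. Condensin, which compacts mitotic chromosomes, had 7 of 8 subunits higher (log2 fold changes from 0.53 to 2.98, median 1.55), among them NCAPD2 at 1.47, NCAPH at 1.78 and SMC4 at 1.51. All 4 GINS helicase subunits and all 4 chromosomal passenger proteins rose (2 of each are in the fixed lists), as did 3 of 4 Ndc80 kinetochore proteins, 2 of 3 Ska proteins, 2 of 5 core cohesin subunits, 2 of 6 origin recognition subunits and 1 of 4 subunits of DNA polymerase alpha-primase. MYBL2, a cell cycle transcription factor, rose by 1.61 ± 0.11 (adjusted p = 8.15e-04) from 122 to 371 CPM, and DNMT1, the maintenance DNA methyltransferase, by 0.95 ± 0.11 (0.00482).

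The following single genes stand as values, without a test of any group. Apart from CXCL12, which lost its call without DMSO 2, their calls were not followed without each library. Without DMSO 2 only 41 of the 395 genes that rose and 5 of the 154 that fell kept their call. GFRA1, a co-receptor of RET, rose by 2.06 ± 0.18 (adjusted p = 0.00142) from 87.9 to 365 CPM, NPY1R, a neuropeptide Y receptor, by 1.74 ± 0.35 (0.0345), and VAV3, a guanine nucleotide exchange factor, by 1.46 ± 0.23 (0.0139). PRLR, the prolactin receptor, rose by 1.08 ± 0.22 (0.0323), a call lost after GC correction as the fold change shrank (0.68 ± 0.28, 0.171). CXCR4, a chemokine receptor, fell by 1.26 ± 0.21 (0.0157) while its ligand gene CXCL12 rose by 1.79 ± 0.40 (0.0465). PSAP, a precursor of lysosomal activator proteins, fell by 0.64 ± 0.10 (0.0124), GUSB, a lysosomal glucuronidase, fell by 0.76 ± 0.11 (0.0107) and GRN, which encodes progranulin, fell by 0.60 ± 0.13 (0.0425). H2AZ1 and H1-0, histone genes with polyadenylated transcripts, rose by 0.71 ± 0.12 (0.0174) and 0.69 ± 0.12 (0.0183).

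The first pattern weighed was the set of 549 called genes, since the libraries differ in GC trend, which does not follow treatment alone, as the largest difference in GC correlation within a group, 0.993, was 2.21 times that between the group means, 0.449. Removal of the GC and length trend argues against that trend itself as the whole cause, as 93.1% of the called genes kept call and sign. It does not speak to other differences between samples that go along with the trend. The correction was not tried on the split with 1260 calls below. DMSO 1 and enterolactone 5 are the ends of the gradient. Without them the higher G2/M, G1/S, DNA repair and oestrogen-induced lists each kept at least 74.9% of their median. The lower 95% limits of a bootstrap over members, which are not independent, ran from 54.1%, and immediate early genes kept 48.1%. The higher medians were thus also seen in the libraries that remained. Whether these 2 libraries are a source of the higher lists cannot be decided from this. The lists were picked as higher with all 6 libraries, no other pair was left out for them, and the bootstrap did not resample libraries. For the called genes these 2 libraries stay open as a source: without them 99.6% kept their sign and at least 50% of their log2 fold change, but any removal of 1 library per group left 100% of the genes with a value so, also in the split with 1260 calls below, and the choice of called genes thus fixed the outcome. With 10 splits of 6 libraries no share under 0.05 can be had: 2 of the 10 splits called at least 549 genes (the real split, and one with 1260) and at least 395 in one direction (the other with 875), and 1 of 10, the real one, gave an oestrogen-induced list as extreme (-log10 p 10.6, highest other 9.20). The split with 1260 calls sets DMSO 1, DMSO 2 and enterolactone 2 against the other libraries, which parts them by the sign of their GC trend and so points to a structure of the samples; with that sign as a term beside treatment 907 genes were higher and 595 lower, but the sign of the separated 549 was fixed in advance, and a response to enterolactone and this structure may both underlie the calls, as open hypotheses.

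The second pattern was the lower replication-dependent histone list beside higher replication genes. The libraries were primed with oligo-dT, and most of these histone mRNAs lack a poly(A) tail, so the combination says little about time spent in S phase. The GC and length trends are argued against as the whole cause only within the camera test, where after their removal the list stayed past the threshold (adjusted p = 0.0109, median -0.20). Before their removal the list was not past it with an estimated correlation (0.457) or by fry (0.142), nor by camera without DMSO 5 (0.0729) or enterolactone 5 (0.147), so the list itself stays uncertain. Lower carry-over of RNAs without a poly(A) tail in the enterolactone libraries may contribute and cannot be told apart from lower histone expression, because only 3 of 30 other such RNAs were measured, with a median of -0.23 and an error of 1.04.

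The third pattern was the fall of TGFBI, CCN2 and, outside the fixed lists, of SMAD3 by 0.69 ± 0.11 (adjusted p = 0.0139), PMEPA1 by 0.91 ± 0.14 (0.0111) and CDKN2B by 0.85 ± 0.13 (0.0130), all known as part of the TGF-beta response. Lower TGF-beta signalling is a candidate explanation, tested on other TGF-beta targets, chosen without any gene seen to fall or in the fixed lists: 15 of 18 were negative with a median of -0.18, and camera gave 0.00630, or an adjusted p = 0.0126 over the 2 lists chosen after the data were seen. The adjusted p was 0.504 with an estimated correlation and 0.0241 after GC and length correction. The 3 positive members were KLF10 at 0.52 ± 0.14 (edgeR adjusted p = 0.0769), SKIL at 0.42 and ADAM19 at 0.32. Called genes had been left out in choosing the list, so its count of calls says nothing, and no protein or pathway measurement was analysed here.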
